A study of Homo sapiens with 6 samples.

How the data were processed

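Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in T47D-MTVL cells, a derivative of the T47D human breast cancer cell line that carries an integrated reporter driven by a mouse mammary tumour virus promoter. Per the labels' protocols, cells were kept in medium with hormone-depleted serum and then without serum, exposed to 10 nM R5020, a synthetic progestin, and fixed with formaldehyde. Antibodies against the kinase CDK2 and against the poly(ADP-ribose) polymerase PARP1 were used on cells at 0, 5 and 30 min, which gave 6 libraries, with 1 library for each antibody and time. The 0 min cells received no hormone.

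The values are read counts deposited by the authors as whole numbers in consecutive windows of 10 kb along chromosomes 1 to 22 and X, with 1 column per library and without normalization. Reads were aligned with Bowtie 1.0.0 to hg19 (GRCh37), per the submitters' processing notes. How duplicate reads, reads with several matches and read quality were handled is not given in the sources used here. The mitochondrial chromosome, chromosome Y, an input library and a spike-in were not analysed here.

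Of 303641 windows, 278395 had a mean of at least 10 counts over the 6 libraries and were compared. Another 21207 windows held 0 reads in all 6 libraries. Each library was scaled by its total, which lay between 40097131 and 63448449 reads. For each of 9 comparisons between 2 libraries, a window was called where the depth-scaled ratio was at least 2 or at most 0.5 and a two-sided exact binomial test, conditional on the sum of both counts and adjusted by Benjamini-Hochberg, gave a value under 0.05. With 1 library per antibody and time there was no replicate check, so this call compares the 2 libraries and not the conditions, and its 95% intervals cover counting error only. A ratio against a library with 0 reads is given as a lower bound with 3 counts per library as the floor. This bound makes no allowance for duplicated fragments, so the true ratio may lie nearer 1. On Poisson libraries simulated with 100 windows changed 3-fold in each direction, the call found 99 to 100% of the raised and 89 to 99% of the lowered windows over the 9 comparisons, with 0 to 3 false calls among 278395 windows.

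Reads from duplicated fragments are not independent, so a dispersion was added after the counts had been seen. Per library it is the robust variance of the difference between neighbouring windows over its Poisson expectation, and equals 1 for independent reads. It also contains real differences between neighbouring windows. Per comparison it is the robust variance around the local ratio, taken over 20 windows on each side. Calls were repeated on counts divided by the dispersion of the comparison. Calls were also counted in libraries simulated without any change, in which each fragment was read several times, with the number of reads per fragment adjusted until the simulated pair met the dispersion of the comparison. A first simulation at the dispersion of the single libraries gave more calls than observed in all 9 comparisons. It was replaced because the dispersion of its pairs exceeded that of the data, for PARP1 at 30 against 0 min with 6.91 against 4.38. For correlations of 1 Mb blocks the first simulation was kept, which overstates their noise. The adjusted simulation still counts real local changes as noise, and its agreement with a number of calls does not show that nothing changed. Widened intervals of chromosome and block ratios use the dispersions of the single libraries, and those of windows called after the dispersion use that of the comparison. The widened intervals of CDK2 in the windows higher for PARP1 at 30 min use those of the single libraries.

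Shares of reads per chromosome were planned before the data were examined. Ratios in blocks of 1 Mb with a mean of at least 5000 reads, of which there were 2827, were added afterwards. Windows named in the text were fixed by a rule before the data were examined, namely the 10 higher and 10 lower called windows per comparison with 0 min whose interval bound lay farthest from 1, with at most 1 per 100 kb. Windows called after division by the dispersion, and the blocks, were named after their values had been seen. Positions are 1-based in hg19. The gene table at hand was of another build (GRCh38.p14), so windows were not assigned to genes, and neither the 9 gene lists fixed beforehand nor promoter classes were evaluated.

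Alternatives planned before the data were examined were TMM factors from edgeR 4.0.16, median-of-ratios size factors from DESeq2 1.42.0, scaling on the windows with the lowest means, other count minimums, other fold limits, thinning of all libraries to 40097131 reads and leaving out the 1% of windows with the highest means. These tools served for scaling factors only. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.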

Results

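The study addressed the activation of PARP1 by CDK2 in the response of breast cancer cells to progestin. Occupancy of CDK2, a cyclin-dependent kinase, and of PARP1, an enzyme that attaches ADP-ribose chains to proteins, was profiled by ChIP-seq in T47D-MTVL cells before hormone and after 5 and 30 min of 10 nM R5020. The 3 CDK2 libraries held 45111064 reads at 0 min, 57793168 at 5 min and 40097131 at 30 min. The 3 PARP1 libraries held 55772389, 58495554 and 63448449 reads. The median window of 10 kb held between 130 reads, in CDK2 at 30 min, and 208 reads, in PARP1 at 30 min. No antibody and time had a second library, so no value below carries an error between replicates.

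The 6 libraries differed in how evenly reads lay along the genome. Across windows, which are not independent replicates, the Spearman correlation was 0.855 between CDK2 and PARP1 at 0 min and 0.856 between PARP1 at 0 and 30 min. It was 0.590 between CDK2 at 0 and 5 min, 0.609 between CDK2 at 0 and 30 min and 0.424 between CDK2 at 5 and 30 min, the lowest of all pairs. The dispersion between neighbouring windows was 7.43, 52.5 and 24.1 for CDK2 at 0, 5 and 30 min, and 6.11, 11.4 and 8.62 for PARP1. In the CDK2 library of 5 min, 3986 windows (1.43%) held 0 reads, against 14 windows in CDK2 at 0 min, 588 in CDK2 at 30 min and 4, 14 and 4 in PARP1. Among windows in which the other 5 libraries predicted 60 to 100 reads, 7.40% held 0 reads in CDK2 at 5 min and none did in PARP1 at 0 or 5 min. Both of these PARP1 libraries are among those 5, so they helped to set the prediction.

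**Figure D1:**
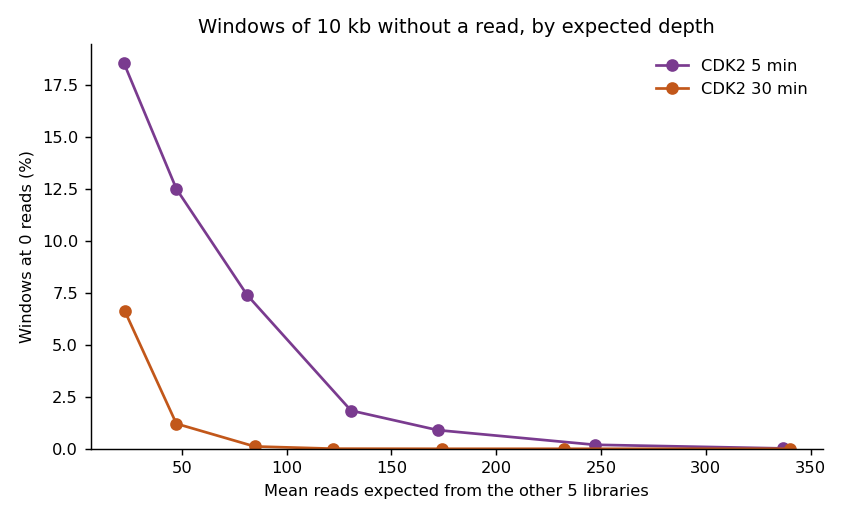
Percentage of 10 kb windows with 0 reads in the CDK2 libraries of 5 and 30 min, against the mean number of reads expected in those windows from the other 5 libraries (reads per window). The percentage fell from 18.6 to 0.0187 in CDK2 at 5 min and from 6.64 to 0 in CDK2 at 30 min as the expected depth rose.

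PARP1 after R5020 was measured against the 0 min library to ask where the enzyme gains or loses occupancy early in the hormone response. At 5 min the share of PARP1 reads was higher on chromosomes 19, 22, 17, 16 and 20, the 5 highest of 23, and lower on chromosomes 4 and 13, the lowest. On chromosome 19 it went from 1.15% to 1.32% of reads, a ratio of 1.15 with a widened 95% interval of 1.13 to 1.16. On chromosome 22 the ratio was 1.14 (1.13 to 1.16), on chromosome 17 it was 1.09 (1.08 to 1.10), on chromosome 16 it was 1.08 (1.07 to 1.09) and on chromosome 20 it was 1.07 (1.07 to 1.08). Chromosome 4 fell to a ratio of 0.947 (0.942 to 0.952) and chromosome 13 to 0.952 (0.946 to 0.958). The widened interval lay above 1 for 11 chromosomes and below 1 for the other 12.

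The 1 Mb block with the highest PARP1 ratio at 5 min was 1 to 1000000 on chromosome 19, with 9167 against 6535 reads and a ratio of 1.34 (widened 95% interval 1.22 to 1.47). The next block of chromosome 19, 1000001 to 2000000, had 1.33 (1.23 to 1.43), the first block of chromosome 11 had 1.33 (1.22 to 1.44), and 139000001 to 140000000 on chromosome 9 had 1.33 (1.26 to 1.40). The lowest ratios were 0.764 (0.691 to 0.846) at 88000001 to 89000000 on chromosome X, 0.779 (0.725 to 0.838) at 63000001 to 64000000 on chromosome 4 and 0.780 (0.727 to 0.837) at 185000001 to 186000000 on chromosome 2. These blocks were chosen after their values had been seen.

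Among single windows, PARP1 at 5 min had 2487 called higher and 4817 called lower than at 0 min, 2.62% of those compared. The highest of those named by the fixed rule was 119400001 to 119410000 on chromosome 4, with 33 reads against 1, a ratio of 31.5 (95% interval 5.27 to 1280). The window 17740001 to 17750000 on chromosome 17 had 281 reads against 67, with a 95% interval of the ratio of 3.05 to 5.30, and 49720001 to 49730000 on chromosome 3 had 119 against 22, a ratio of 5.16 (3.25 to 8.54). Of the 10 lower windows named by the rule, 5 were on chromosome X, and of the 10 higher ones 0. The median window of chromosome X held only 0.478 times that of all compared windows in PARP1 at 0 min. What this low depth contributes to the lower windows was not tested. The foremost, 76420001 to 76430000, had 0 reads against 31 and was at least 10.8-fold lower, and 80750001 to 80760000 had 3 reads against 68, a ratio of 0.0421 (0.00846 to 0.128). Libraries simulated without change at the dispersion of this comparison gave 6320 calls against the 7304 observed. Of the simulated calls, 2274 were higher and 4046 lower. After division by the dispersion 2 windows remained called, both higher, namely 44970001 to 44980000 on chromosome 11 with 568 against 184 reads (ratio 2.94, widened interval 1.95 to 4.56) and 144640001 to 144650000 on chromosome 8 with 410 against 125 reads (3.13, 1.90 to 5.36).

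At 30 min, with scaling by totals, the PARP1 ratio to 0 min lay on the same side of 1 as at 5 min on all 23 chromosomes. It was closer to 1 on those named above. The widened interval lay above 1 for 11 chromosomes and below 1 for 10. The ratio to 0 min was 1.09 (1.08 to 1.10) on chromosome 19, 1.09 (1.08 to 1.10) on chromosome 22, 1.06 (1.05 to 1.07) on chromosome 17, 0.964 (0.960 to 0.968) on chromosome 4 and 0.973 (0.967 to 0.978) on chromosome 13. The block 9000001 to 10000000 on chromosome 21 had the highest ratio, 1.62 (1.51 to 1.73), which came from the window 9820001 to 9830000. Without its 2 windows of highest mean the block 21 9000001, PARP1 30 min against 0 min, had a ratio of 0.986. Next came 85000001 to 86000000 on chromosome 16, with 1.27 (1.23 to 1.32), and 1000001 to 2000000 on chromosome 19, with 1.23 (1.15 to 1.32). The lowest block, 49000001 to 50000000 on chromosome 11, had 0.814 (0.749 to 0.885). Directly between 30 and 5 min, chromosome 19 was lower at 30 min, with a ratio of 0.951, and chromosome 13 was higher, with 1.02.

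PARP1 at 30 min had 1130 windows called higher and 1635 called lower than at 0 min, and 9 windows, 6 higher and 3 lower, were still called after division by the dispersion. The window 9820001 to 9830000 on chromosome 21 rose from 3465 to 10364 reads, a ratio of 2.63 (widened 95% interval 2.42 to 2.85). The window 91850001 to 91860000 on chromosome 1 rose from 1051 to 2844 reads (2.38, 2.05 to 2.77), 20700001 to 20710000 on chromosome 12 from 448 to 1126 (2.21, 1.75 to 2.81), and 39670001 to 39680000 on chromosome 17 from 287 to 694 (2.13, 1.58 to 2.88). The other 2 higher windows were 12670001 to 12680000 on chromosome 1 (3.31, 1.98 to 5.78) and 34600001 to 34610000 on chromosome 14 (2.34, 1.64 to 3.40). The 3 lower windows were 84820001 to 84830000 on chromosome 12 (0.435, 0.301 to 0.623), 25530001 to 25540000 on chromosome 15 (0.369, 0.232 to 0.573) and 59020001 to 59030000 on chromosome 17 (0.434, 0.302 to 0.615). The rule fixed beforehand named other windows, of lower depth. Its foremost were 132540001 to 132550000 on chromosome 2, with 35 reads against 3 (ratio 10.3, 95% interval 3.23 to 52.1), and 10640001 to 10650000 on chromosome 18, with 69 against 10 (6.07, 3.11 to 13.2), among the higher ones, and 57150001 to 57160000 on chromosome 7, with 2 against 29 (0.0606, 0.00701 to 0.240), among the lower ones. Simulation without change gave 2797 calls, 1242 higher and 1555 lower, against the 2765 observed. Between 30 and 5 min, 3629 windows were higher and 2227 lower, against 3480 and 2442 of 5922 simulated calls. After the dispersion 1 was called, 20700001 to 20710000 on chromosome 12, with a ratio of 2.13 (widened 1.63 to 2.80).

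CDK2 was measured at the same times to ask where the kinase is found on chromatin after hormone. At 30 min CDK2 reads were more frequent on chromosomes 22, 19, 16, 17 and 20 and less frequent on chromosomes 4, 13 and X. The share of chromosome 22 went from 0.746% to 0.926%, a ratio of 1.24 (widened 95% interval 1.22 to 1.26), and that of chromosome 19 from 1.18% to 1.42%, a ratio of 1.20 (1.19 to 1.22). The ratio was 1.13 (1.12 to 1.14) on chromosome 16, 1.12 (1.11 to 1.13) on chromosome 17 and 1.12 (1.11 to 1.13) on chromosome 20. It was 0.929 (0.922 to 0.936) on chromosome 4, 0.946 (0.937 to 0.956) on chromosome 13 and 0.954 (0.944 to 0.965) on chromosome X. The widened interval lay above 1 for 10 chromosomes and below 1 for 10.

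The block 139000001 to 140000000 on chromosome 9 had the highest CDK2 ratio at 30 min, 1.58 (1.47 to 1.71), with 22339 against 15878 reads. The blocks 1000001 to 2000000 and 1 to 1000000 on chromosome 19 followed with 1.57 (1.41 to 1.75) and 1.53 (1.35 to 1.75), and 60000001 to 61000000 on chromosome 20 had 1.53 (1.41 to 1.67). The lowest were 63000001 to 64000000 on chromosome 4, with 0.725 (0.642 to 0.818), and 85000001 to 86000000 on chromosome 5, with 0.734 (0.664 to 0.812). The same block of chromosome 4 was among the 3 lowest for PARP1 at 5 min.

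At 5 min, with scaling by totals, the CDK2 ratio lay on the other side of 1 than at 30 min on most chromosomes, with 5 of 23 on the same side. This tally rests on that scaling. The other scalings raise the CDK2 log2 ratios at 5 min by 0.0633 to 0.140, and the lowest of a chromosome was -0.0635, on chromosome 22. The ratio to 0 min was 0.957 (0.934 to 0.980) on chromosome 22, 0.959 (0.947 to 0.972) on chromosome 16, 0.972 (0.960 to 0.983) on chromosome 17 and 0.977 (0.959 to 0.996) on chromosome 19, and 1.02 (1.01 to 1.03) on chromosome 4 and 1.02 (1.01 to 1.04) on chromosome 13. Chromosome X was lower at both times, with 0.987 (0.974 to 0.999) at 5 min, as was chromosome 18, with 0.981 (0.967 to 0.995) at 5 min and 0.982 at 30 min. The widened interval lay above 1 for 6 chromosomes and below 1 for 10. The highest block was 1 to 1000000 on chromosome 1, with 1.38 (1.30 to 1.46), but 2 windows held most of its reads. Without them it had 1926 against 1867 reads, a ratio of 0.805. The next was 61000001 to 62000000 on chromosome 4, with 1.25 (1.11 to 1.39), and the lowest 8000001 to 9000000 on chromosome 4, with 0.759 (0.645 to 0.895). Between 30 and 5 min the ratio reached 1.30 on chromosome 22 and 0.909 on chromosome 4.

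**Figure D2:**
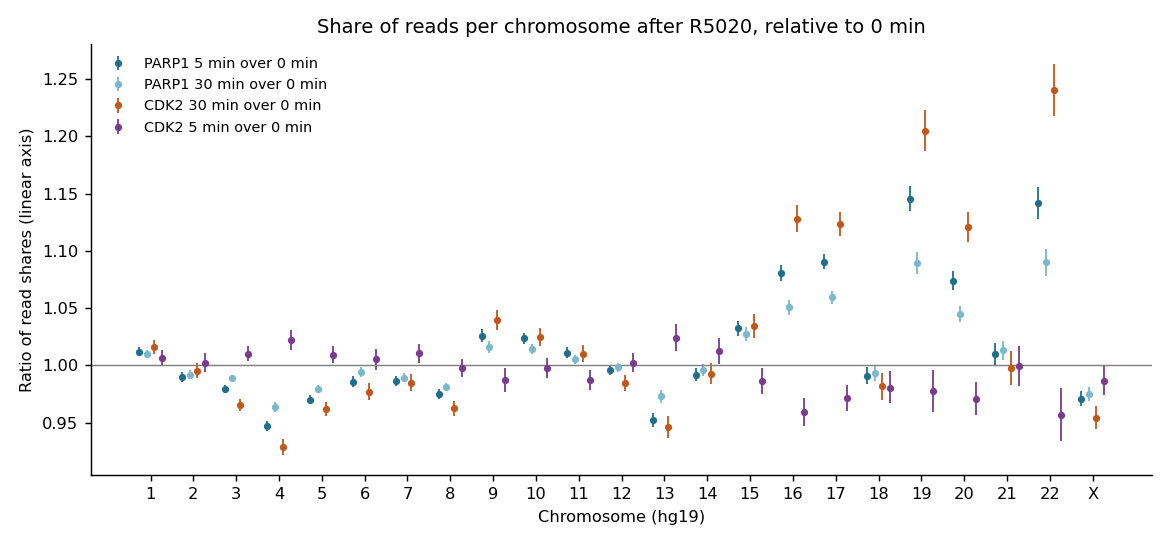
Ratio of the share of reads on each chromosome (hg19, horizontal axis) after R5020 to that at 0 min (vertical axis, linear, not starting at 0), for PARP1 and CDK2 at 5 and 30 min. Points are 1 library against 1 library and bars are widened 95% intervals. PARP1 at both times and CDK2 at 30 min lie above 1 on chromosomes 16, 17, 19, 20 and 22, with up to 1.24, and CDK2 at 5 min lies below 1 there. The side of CDK2 at 5 min rests on scaling by totals, since other scalings raise its log2 ratios by 0.0633 to 0.140.

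CDK2 had 17284 windows called higher and 45020 called lower at 5 min than at 0 min, and 15204 higher and 32036 lower at 30 min. With scaling on the windows of lowest mean, the 5 min counts became 25717 higher and 37929 lower. Libraries simulated without change also gave more lower than higher calls, as given below. None of the windows named by the rule for CDK2 against 0 min was called after division by the dispersion. All 10 lower windows named by the rule at 5 min held 0 reads. The foremost was 148370001 to 148380000 on chromosome 3, with 0 reads against 301, at least 129-fold lower, although CDK2 at 30 min had 201 reads there and PARP1 225 at 5 min. Likewise 134090001 to 134100000 on chromosome 5 had 0 reads against 292, at least 125-fold lower, and 228 reads at 30 min. The foremost higher window was 81480001 to 81490000 on chromosome 10, with 109 reads against 0, at least 28.4-fold higher, but 15 reads at 30 min. At 30 min the lower windows named by the rule also held 0 reads, led by 92170001 to 92180000 on chromosome 4, with 186 reads at 0 min, at least 55.1-fold lower, where CDK2 had 116 reads at 5 min. The foremost higher window was 63350001 to 63360000 on chromosome X, with 60 reads against 0, at least 22.5-fold higher, and 0 reads at 5 min.

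Simulated libraries without change gave 62569 calls for CDK2 at 5 min and 42968 at 30 min, against the 62304 and 47240 observed. The simulated calls were 18850 higher and 43719 lower at 5 min, and 13588 higher and 29380 lower at 30 min. The excess of lower over higher windows therefore does not show a loss of CDK2. After division by the dispersion, 1 window was called in each comparison with 0 min. At 5 min it was 43090001 to 43100000 on chromosome 8, with 3341 against 1140 reads (ratio 2.29, widened interval 1.65 to 3.23). At 30 min it was 138160001 to 138170000 on chromosome 9, with 638 against 163 reads (4.40, 2.31 to 9.08). The window on chromosome 8 held 1140 reads already at 0 min, against 149 in the median window of that library. Reads shared between repeated copies were not examined there. Between 30 and 5 min, 51194 windows were higher and 42070 lower, against 48979 and 39145 of 88124 simulated calls. With scaling on the windows of lowest mean the majority turned, with 46306 higher and 47832 lower. After the dispersion 2 were called. These were 9820001 to 9830000 on chromosome 21, higher at 30 min (2.77, 1.97 to 3.95), and the window on chromosome 8 just named, lower at 30 min (0.182, 0.0947 to 0.321).

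CDK2 and PARP1 were then set against each other at each time. A ratio of 2 antibodies also holds their different yields, so it describes only where reads lay. At 0 min the ratio of CDK2 to PARP1 ran from 0.993 (widened 95% interval 0.989 to 0.997) on chromosome 8 to 1.02 (1.01 to 1.03) on chromosome 19, with the interval above 1 on 4 chromosomes and below 1 on 3. At 5 min chromosome 22 had the lowest ratio, 0.844, and chromosome 4 the highest, 1.08. At 30 min chromosome 22 had the highest, 1.15, and chromosome 4 the lowest, 0.967.

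After division by the dispersion 13, 9 and 10 windows separated the antibodies at 0, 5 and 30 min, and 6 of them did so at all 3 times. The window 560001 to 570000 on chromosome 1 held 38577 CDK2 and 7561 PARP1 reads at 0 min, a ratio of 6.31. The ratio was 7.87 at 5 min and 7.69 (widened 95% interval 7.02 to 8.44) at 30 min. The window 134260001 to 134270000 on chromosome 5 had 5.47 (5.09 to 5.89), 6.32 (5.34 to 7.52) and 6.35 (5.57 to 7.26) at the 3 times. The others of the 6 were 570001 to 580000 on chromosome 1, 79940001 to 79950000 and 134250001 to 134260000 on chromosome 5, and 125600001 to 125610000 on chromosome X, with ratios at 0 min between 3.45 and 6.01. The median window at 0 min held only 149 CDK2 and 182 PARP1 reads. Whether the reads of these 6 windows come from mitochondrial DNA was not settled, as given below, so they are not read as sites of CDK2. In the other direction, 68340001 to 68350000 on chromosome 6 was lower for CDK2 at 0 min only (0.258, 0.127 to 0.484). The window 9820001 to 9830000 on chromosome 21 was lower for CDK2 at 5 min (0.314, 0.230 to 0.423) and at 30 min (0.482, 0.413 to 0.561), and 91850001 to 91860000 on chromosome 1 was lower at 30 min (0.456, 0.335 to 0.614).

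Without the dispersion, CDK2 was higher than PARP1 in 1231 and lower in 2040 windows at 0 min, in 22316 and 47353 at 5 min, and in 10701 and 28775 at 30 min. Simulation without change gave 3685, 66572 and 37974 calls. These were 1472 higher and 2213 lower at 0 min, 21150 and 45422 at 5 min, and 11101 and 26873 at 30 min.

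**Figure D3:**
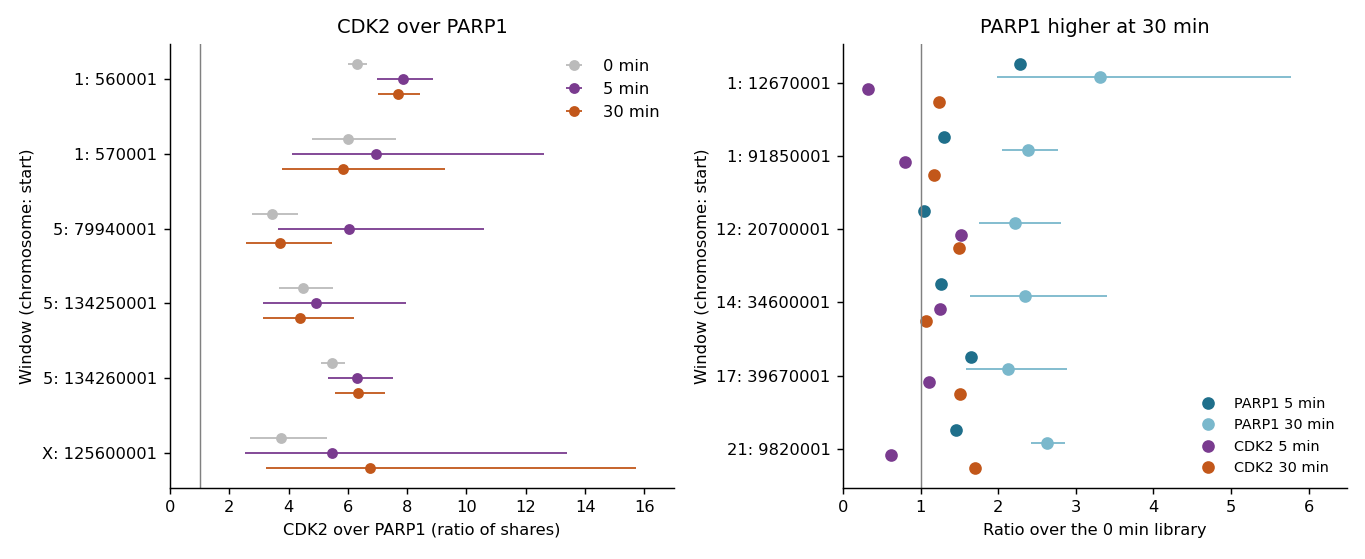
Left, ratio of CDK2 to PARP1 shares at 0, 5 and 30 min (horizontal axis, no unit) in the 6 windows of 10 kb higher for CDK2 at all 3 times, with widened 95% intervals. Right, ratio over the 0 min library for both antibodies at 5 and 30 min in the 6 windows higher for PARP1 at 30 min, with widened 95% intervals for PARP1 at 30 min. Windows are labelled by chromosome and start in hg19. The highest ratio on the left is 7.87 and on the right 3.31.

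Whether both proteins changed at the same places was asked from the overlap of called windows. At 5 min, 2555 windows were called for both antibodies, of which 1344 moved the same way and 1211 opposite ways, an odds ratio of 0.769 (95% interval 0.644 to 0.918). Both were higher in 256 windows, against 154 expected from independent lists, and both lower in 1088 against 779. The mixed pairs also exceeded independence, with 539 against 299 and 672 against 402. At 30 min, 597 of 930 windows moved the same way, an odds ratio of 2.70 (2.04 to 3.57), with 173 windows higher for both against 61.7 expected and 424 lower for both against 188. The mixed pairs exceeded independence here too, with 144 against 89.3 and 189 against 130. For the overlap of CDK2 and PARP1 changes at 30 min the odds ratio depended on the settings, with 4.48 at a limit of 1.5-fold, 3.71 after thinning and 9.13 for windows with a mean of at least 100 counts. The intervals of the odds ratios come from the numbers of windows and treat each window as independent. Neighbouring windows are not, so these intervals are too narrow, and they hold no error between libraries.

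In 1 Mb blocks the log2 ratios of CDK2 and PARP1, which share no library, had a correlation of 0.874 at 30 min and -0.379 at 5 min. Blocks are not independent replicates. CDK2 at 30 min and PARP1 at 5 min had a correlation of 0.908. Both of the positive relations held within each of 23 chromosomes, with within-chromosome values of at least 0.418 and 0.561. At single windows the same correlations were 0.128, -0.0165 and 0.146. Across whole chromosomes, with scaling by totals, the sign of the CDK2 log2 ratio at 30 min matched that of PARP1 on 22 of 23 chromosomes at 30 min and at 5 min. CDK2 and PARP1 at 5 min matched on 4. The other scalings raise the CDK2 log2 ratios at 5 min by 0.0633 to 0.140, so the count of 4 depends on the scaling. They raise those at 30 min by 0.0493 to 0.0583, against -0.0338 on chromosome 6 and -0.0219 on chromosome 7 with scaling by totals. The PARP1 log2 ratios rise less, by 0.00605 to 0.0213 at 30 min and 0.0130 to 0.0251 at 5 min. Both counts of 22 therefore depend on the scaling too.

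**Figure D4:**
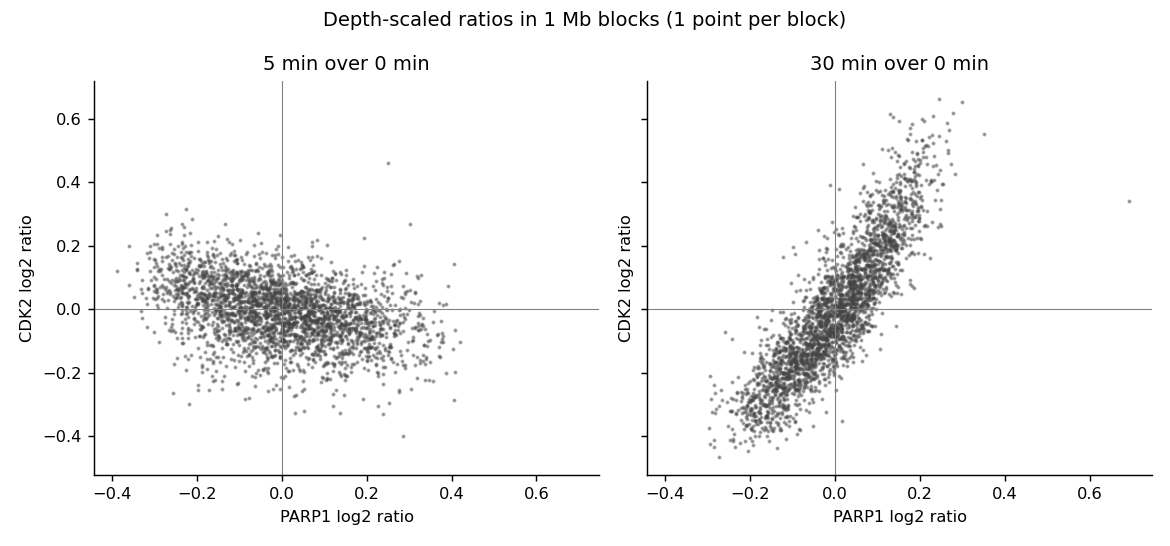
Log2 ratio of CDK2 (vertical axis) against log2 ratio of PARP1 (horizontal axis) over the 0 min library in 2827 blocks of 1 Mb, 1 point per block, at 5 min (left) and 30 min (right). The correlation is -0.379 at 5 min and 0.874 at 30 min.

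Within each antibody the 5 and 30 min comparisons share the 0 min library, which alone gives overlap. For PARP1, 680 of 692 windows called at both times (98.3%) moved the same way, against 96.7% in simulated libraries without change. Windows higher at both times numbered 364 against 10.1 from independent lists, 36.1 times as many, and windows lower at both times 316 against 28.3, 11.2 times as many. Simulation without change gave 39.7 and 12.3 times, so the shared library can account for this overlap. Over 1 Mb blocks the covariance of the PARP1 log2 ratios at 5 and 30 min was 0.0155 against 0.000748 without change, and the correlation 0.941 against 0.396. For CDK2, 9118 of 13191 windows (69.1%) moved the same way against 74.3% without change. Windows higher at both times numbered 2358 against 944 from independent lists, and windows lower at both times 6760 against 5181, 1.30 times as many. Simulation without change gave 3.32 times for the higher and 1.51 times for the lower windows. The block covariance was -0.00703 against 0.00109 without change, and the correlation -0.358 against 0.175.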

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

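The chromosome shares and overlap odds ratios were planned before the data were examined, and the tests of blocks, windows at 0 and single windows were chosen after the results were seen. With 1 library per antibody and time none of the differences between antibodies or times was tested.

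As shares of all reads, CDK2 and PARP1 lay on opposite sides of 1 at 5 min on 14 chromosomes, with both widened intervals. CDK2 was above and PARP1 below 1 on 6 of the 14. The CDK2 ratios were 1.01 on chromosome 3, 1.02 on chromosome 4, 1.01 on chromosome 5, 1.01 on chromosome 7, 1.02 on chromosome 13 and 1.01 on chromosome 14. CDK2 was below and PARP1 above 1 on 8, with CDK2 ratios of 0.987 on chromosome 9, 0.987 on chromosome 11, 0.986 on chromosome 15, 0.959 on chromosome 16, 0.972 on chromosome 17, 0.977 on chromosome 19, 0.971 on chromosome 20 and 0.957 on chromosome 22. The direction on these 8 rests on scaling by totals, since other scalings raise the CDK2 log2 ratios at 5 min by 0.06 to 0.14, against decreases of at most 0.06. They also raise the PARP1 log2 ratios at 5 min, by 0.0130 to 0.0251. The PARP1 log2 ratio of -0.0120 on chromosome 14 is smaller in size than each of these shifts. That of -0.0205 on chromosome 7 is smaller than the largest. The opposition on these chromosomes rests on the scaling too. The odds ratio for the direction of windows called for both antibodies was 0.769 at 5 min and 2.70 at 30 min.

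The shift of reads between chromosomes and 1 Mb blocks, shared by PARP1 at both times and CDK2 at 30 min, did not come from a few strong sites, since the slope of the median window ratio of a block on its total ratio was at least 0.979 in these 3 comparisons. Random loss of distinct fragments alone is argued against, since it would leave comparisons without a shared library uncorrelated, while CDK2 at 30 min and PARP1 at 5 min had a correlation over blocks of 0.908, and of at least 0.561 within each of 23 chromosomes. Loss that depends on base composition is not covered by this. A bias of single libraries towards base composition may account for the shift and cannot be told apart from the R5020 treatment, because no genome sequence was used here and no library was repeated. Neither is decided by the Spearman correlation over blocks of 0.102 between the CDK2 to PARP1 ratio at 0 min and the PARP1 ratio of 5 to 30 min, or by the correlation of 0.874 between antibodies at 30 min.

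The 3986 windows at 0 reads in CDK2 at 5 min may come from a library of few distinct fragments that were each read many times, but this was not settled. The number of reads per fragment implied by the share of windows at 0 differed 2.97-fold over expected depths from 15 to 400 reads, from 13.3 at the lowest depth to between 31.2 and 39.5 from 60 reads up, where a constant number was predicted. The test was first limited to depths from 60 reads up, where the prediction was met, and was then widened to all depths because that limit had no prior reason. CDK2 lost from domains wider than 1 window remains open, since neighbouring windows were both at 0 in 118 pairs, 1.61 times the number expected from depth (95% interval 1.33 to 1.92), while pairs 20, 100 and 500 kb apart gave 1.34, 1.59 and 1.25. An effect of R5020 for 5 min on CDK2 cannot be told apart from the library itself, the only one of that antibody and time, in which 1.43% of windows were at 0.

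The 6 windows higher in PARP1 at 30 min lay above the surrounding megabase, whose median ratio was 1.02 against at least 2.13 in the windows. These windows were picked for a ratio of at least 2. Apart from the block on chromosome 21 raised by its own window, the highest 1 Mb block ratio was 1.27. The comparison could therefore hardly have come out otherwise and only describes the windows. Reads shared between repeated copies may contribute, as the window on chromosome 21 held 19 times the library median already at 0 min, and this stretch of its short arm is known in hg19 to carry part of a ribosomal RNA repeat. The windows at 12670001 on chromosome 1 and 34600001 on chromosome 14 held 0.467 and 1.04 times the median and gave no sign of it in their depth. Those at 91850001 on chromosome 1 and on chromosomes 12 and 17 held 5.77, 2.46 and 1.58 times the median. There and on chromosome 21, shared reads cannot be told apart from a true high level. The handling of reads with several matches is not given in the sources used here, and repeats in the other windows were not examined. An effect of R5020 for 30 min stays open. CDK2 at 30 min, a library not used to pick them, had a higher ratio than the surroundings in 6 of the 6 windows. The difference was slight on chromosome 14 (1.07 against 1.06) and at 12670001 on chromosome 1 (1.23 against 1.19). The surroundings lay below the widened interval only on chromosome 12 (0.805 against 1.49, 0.858 to 2.60) and chromosome 21 (1.08 against 1.69, 1.38 to 2.08). That interval excluded 1 only on chromosome 21.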

How the results depend on the processing

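The number of called windows stayed within 1.5 times its value in all 9 comparisons under TMM factors, median-of-ratios size factors, scaling on low windows, no filter, a mean of at least 30 counts, thinning and without the 1% highest windows. The other fold limits, by their own construction, moved it in all 9. The numbers at 1.5-fold, at 3-fold and with counts divided by the dispersion were 125798, 25361 and 1 for CDK2 5 min against 0 min, 110473, 14154 and 1 for CDK2 30 min against 0 min, 154818, 43204 and 2 for CDK2 30 min against 5 min, 44105, 850 and 2 for PARP1 5 min against 0 min, 25229, 303 and 9 for PARP1 30 min against 0 min, 36038, 753 and 1 for PARP1 30 min against 5 min, 25480, 407 and 13 for CDK2 against PARP1 at 0 min, 134145, 28314 and 9 for CDK2 against PARP1 at 5 min, 99660, 11807 and 10 for CDK2 against PARP1 at 30 min. The division was chosen after seeing the data and leaves few calls since the effective counts are fewer, and none of the 80 windows named by the rule was called. Those 80 were called under the 3 scalings, thinning and 3-fold. Scaling on low windows turned the majority of calls for CDK2 30 min against 5 min to 46306 higher and 47832 lower. Of the 48 calls made after the dispersion, 48 held under TMM factors, 47 under median-of-ratios size factors, 47 after thinning and 28 at 3-fold. Scaling on low windows raised the log2 ratio of all windows by 0.14 for CDK2 at 5 over 0 min and by 0.11 for CDK2 over PARP1 at 5 min.

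For the overlap of CDK2 and PARP1 changes at 30 min the odds ratio was 4.48 at 1.5-fold, 3.71 after thinning and 9.13 with a mean of at least 100 counts (added after seeing the data), and for the overlap of CDK2 and PARP1 changes at 5 min 0.602 with that minimum. For the overlap of CDK2 changes at 5 and 30 min it was 3.94, and 2.31 at 1.5-fold and 3.59 under TMM factors. The cause was not tested. The lowest library correlation was 0.452 as Pearson of log2 values and 0.448 without filter, and the highest 0.882 and 0.862. The alternatives for chromosomes and blocks were added after seeing the data. Of 92 chromosome ratios, 88 stayed within their interval without the 1% highest windows and 70 as median window ratios, where chromosome 4 had 0.919 for CDK2 at 30 min and chromosome 19 0.958 for CDK2 at 5 min. The block correlation, CDK2 5 min against 0 min and PARP1 5 min against 0 min, was -0.323 from median window ratios and -0.592 in 5 Mb blocks, and at 30 min 0.830 and 0.945, with 0.864 without chromosomes 16, 17, 19, 20 and 22. Of the 80 named blocks, 78 stayed within their interval without their 2 highest windows (chosen after seeing the data) and 2 reversed, block 1 1, CDK2 5 min against 0 min, to 0.805 and block 21 9000001, PARP1 30 min against 0 min, to 0.986. As median window ratios, 75 of 77 stayed and 2 moved, and 3 entries in these 2 blocks held too few compared windows for a median. The alternatives planned for gene lists and promoter classes were not run, because windows were not assigned to genes. No paired analysis was possible because each comparison set 1 library against 1 and the labels give no replicate numbers, which also left no replicate to leave out. The antibodies share 3 times, which are different conditions and were not used as replicates.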

Other observations

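All tests in this part were chosen after the data were seen.

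Reads per window differed between chromosomes, on most of them in the same direction in all 6 libraries. The libraries lay on both sides of their median window on chromosomes 1, 16 (0.919 to 1.08) and 20 (0.914 to 1.05). Relative to the median window of each library, the median window held 1.41 to 1.53 times as many reads on chromosome 12, 1.33 to 1.53 on chromosome 8, 1.16 to 1.41 on chromosome 17, 1.28 to 1.35 on chromosome 3 and 1.21 to 1.32 on chromosome 5, but 0.446 to 0.490 on chromosome X, 0.584 to 0.731 on chromosome 19, 0.611 to 0.815 on chromosome 22 and 0.769 to 0.824 on chromosome 2. Of the 20 blocks of 1 Mb with the most reads, 19 lay on chromosome 3 and 1 on chromosome 10. The highest, 193000001 to 194000000 on chromosome 3, held 3.83 times the median block, and at least 3.50 times it in each of the 6 libraries. No input library was analysed, so these densities cannot be separated into occupancy and background and are not read as occupancy of CDK2 or PARP1.

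Windows that rose against their surroundings in both antibodies at 30 min were looked for, as a hypothesis that both share sites of local gain. Among 267939 windows with at least 50 reads in both 0 min libraries, 1947 were at least 1.5-fold above their local median in both, against a mean of 1471 and a maximum of 1617 in 1000 circular shifts of 1 antibody along the genome, a ratio of 1.32. Both were lower in 2805 windows against 2053, whereas opposite pairs numbered 1640 against 1734 and 1552 against 1742. The excess may reflect shared sites of local gain, but local base composition would also move both antibodies alike and was not examined, and most of the 1947 are the number that chance gives. The foremost was 129670001 to 129680000 on chromosome 10, where PARP1 went from 84 to 168 and 247 reads and CDK2 from 72 to 132 and 258. It was followed by 43390001 to 43400000 on chromosome 1, with PARP1 at 90, 177 and 274 reads and CDK2 at 129, 245 and 363. In the next 4, on chromosomes 2, 17, 13 and X, the depth-scaled CDK2 ratio at 5 min was below 1, with 0.790, 0.813, 0.288 and 0.548.

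The 6 windows higher for CDK2 than for PARP1 at all 3 times are a candidate for reads of mitochondrial DNA placed on its nuclear copies, which are known in hg19 at the start of chromosome 1. A common source would keep the windows in a fixed proportion. Relative to 560001 to 570000 on chromosome 1, the excess over the surroundings in the other 5 windows varied across the 6 libraries by a median of 12.3% (coefficient of variation, 8.11% to 26.5%). Neither a variation under 5% nor one over 50%, the bounds chosen for and against, was met, and mitochondrial reads were not analysed here. The bound of 5% made no allowance for the dispersion of the libraries. That was 8.62 in PARP1 at 30 min, where the window on chromosome X held 129 reads. Such noise can exceed 5% in a fixed proportion, so the test could not decide.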
